A study of Homo sapiens with 24 samples.

How the data were processed

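RNA was measured on 24 Affymetrix Human Gene 2.1 ST arrays. They cover 2 human cell lines, HEK293 and BJ-hTERT, that carry an inducible HA-tagged YWHAE-NUTM2 fusion gene. Each line was treated with doxycycline or with the water vehicle (mock) and sampled 24 or 72 h later, which gives 8 groups of 3 arrays. The titles of all 3 HEK293 doxycycline arrays at 24 h spell the line HEK239, which was read as a typing error for HEK293. Arrays of different groups within a line, these included, correlated at r = 0.956 to 0.977 across genes, and arrays of different lines at 0.775 to 0.800. The deposited values are log2 probe set intensities on the scale of robust multi-array average (RMA). The submitters' processing notes credit GCOS, RMA and Affymetrix Expression Console, and the series design text names oligo and limma, all without a version. Which arrays were normalised together, the array library version and the genome build are not given in the sources used here, so no chromosomal positions are printed.

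The deposited table held 352859 probe sets on 24 arrays, with 0 missing values, from -0.193 to 13.8 log2. The probe table named 275431 of them, 257971 with 1 gene symbol and 17460 with several symbols, and 77428 were not listed with a gene. Probe sets with 1 symbol were averaged per gene on the log2 scale, with a median of 8 probe sets per gene over 25029 genes. A gene was tested when its highest group mean reached the 40th percentile of all group means, log2 2.83. This left 17329 genes and removed 7700. Array symbols were matched to current symbols through a table of human genes used for names and neighbours only: 23358 were current, 1621 were updated and 50 found no match. Genes are printed under the array's symbol, with the current symbol beside it at least once where the 2 differ. Genes whose probe sets carry several symbols are not tested as genes, and 2941 of these probe sets carried several names of 1 gene. Another 15141 pairs of probe sets held identical values on all arrays. YWHAE has no probe set named for it and was not analysed here.

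Every comparison between groups came from 1 limma fit (limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table and 1.5.0 of statmod) of 8 group means to all 24 arrays, followed by eBayes. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene is called at an adjusted p under 0.05 with no minimum fold. Values after ± are standard errors (SE) of the limma contrast unless SD is written, with n = 3 arrays per group. The contrasts were doxycycline against mock in each line and time, the difference of that effect between times within a line and between lines within a time, the mean of the 4 effects, and 72 h mock against 24 h mock in each line. The probe sets that name a NUTM2 gene were tested one by one in the same fit on probe sets. Overlaps of calls were tested with a one-sided Fisher's exact test over the genes tested.

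Gene lists of signalling pathways, complexes, metabolic routes and cell types were written from general knowledge. The 46 lists with at least 5 tested members entered camera with its preset correlation of 0.01, adjusted over 46 lists and 4 comparisons together. The same test with a correlation estimated from the data, and fry, were run beside it. For each list the members called over all genes and the members called when adjusted over the list alone were counted. The same lists were tested on the time differences, the line differences and the change over time in mock cells, which was decided after the data were seen.

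The genes named in the text were drawn from those picked by a rule written beforehand, and not every picked gene is printed. For each of the 4 doxycycline comparisons the rule picks the 12 largest called rises and the 12 largest called falls whose 3 doxycycline arrays all lie on 1 side of the 3 mock arrays. It also picks the 4 members of each list with the smallest p, the genes called in both lines at 1 time (up to 10 by the smaller of the 2 changes), the 5 largest called genes for each difference between times or lines, and the 5 largest called rises and falls over time in mock cells. Genes of small RNAs and uncharacterised genes were passed over for the next gene. Any other gene is named with the words that it was chosen after its values were seen.

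The test was tested on simulated data in which 200 of 17329 genes, drawn at random, were changed in the BJ-hTERT comparison at 72 h. The remaining members of the extracellular matrix list were lowered there too and were left out of the false calls. The test recovered 24% of genes changed 1.5-fold and 63% of genes changed 2-fold, with 4 false calls and 0 calls in the other 3 limma comparisons. Of 2 lists called, 1 had not been changed. Noise was drawn independently for each gene, so the list test was not tried on correlated genes. The mean estimates for 2-fold changes were 0.96 and -0.94. Array number limits the precision of every value given.

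Alternatives to the choices above covered the scaling between arrays (median centring, quantile normalisation over all arrays or within each line, and cyclic loess), the filter (none, or the 60th percentile), the gene value (median of probe sets, only brighter probe sets in the mean, 1 test per probe set), and the spread (arrays of 1 line alone, only the groups of a comparison, an intensity trend with robust eBayes, array weights, or replicate number as a block). They also covered the threshold (0.01, or a fold of at least 1.5), the list test, and leaving out each array in turn. Of 2 alternatives added after the data were seen, 1 counted copied probe sets of a gene once and the other added probe sets with several names of 1 gene. Leaving out arrays for the NUTM2 probe sets was also added then. For each comparison, other splits of the same arrays were tested, up to 100 drawn at random. For the time differences the splits of the arrays of 1 line were also counted after the mean doxycycline effect of the line was subtracted from its doxycycline arrays, which was decided after the results were seen.

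The doxycycline dose is not given in the sources used here. The growth protocol also mentions tetracycline, and the series holds no line without the fusion gene treated with doxycycline. The labels number the replicates but do not say that they are separate cultures.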

Results

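Gene expression was measured on 24 arrays from 2 human cell lines carrying a doxycycline-inducible, HA-tagged YWHAE-NUTM2 fusion gene. YWHAE encodes the 14-3-3 epsilon adaptor protein, and its fusion to NUTM2 genes occurs in clear cell sarcoma of the kidney and in endometrial stromal sarcoma. HEK293 is an embryonic kidney line and BJ-hTERT is a foreskin fibroblast line immortalised with telomerase. Doxycycline and mock (water vehicle) cells were taken at 24 and 72 h, with n = 3 arrays in each of the 8 groups. The series title places the interest in signalling and cell migration. Replicate arrays of a group correlated at r = 0.974 to 0.980 across genes, arrays of different groups within a line at 0.956 to 0.977, and arrays of different lines at 0.775 to 0.800 (genes are not independent replicates). Array medians spanned 0.137 log2 and the median residual SD of a gene was 0.236 log2. The labels do not say that replicates are separate cultures, so p-values measure the spread between these arrays only, and the number of arrays limits precision.

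Transcripts of the fusion partner NUTM2 rose strongly with doxycycline in both lines at both times. Among 34 distinct probe sets naming NUTM2 genes, 6 rose in HEK293 at 24 h (median log2 change 3.52, range 2.60 to 4.52) and 11 rose at 72 h (median 3.47, range 2.07 to 5.45). In BJ-hTERT 14 rose at 24 h (median 3.62, range 2.07 to 5.57) and 14 rose at 72 h (median 3.18, range 2.39 to 6.52). None of the 34 fell, and 6 rose in all 4 comparisons. Averaged over those 6, the lowest doxycycline array stood at log2 8.36 against 5.21 for the highest mock array in HEK293 at 24 h, and at 8.39 against 5.70 at 72 h. In BJ-hTERT the same values were 9.11 against 5.39 and 8.53 against 5.69. Over all probe sets of the array, 7 rose in all 4 comparisons, all 7 naming NUTM2 genes (1 is a copy of another), and none fell in all 4. At the gene level NUTM2B rose by 2.16 ± 0.29 and 2.33 ± 0.29 log2 in HEK293 at 24 and 72 h and by 1.90 ± 0.29 and 1.95 ± 0.29 in BJ-hTERT. All 7 name several NUTM2 paralogs, so which of them was read was not separated. The count of 6 became 0 when each line or each comparison was fitted with its own arrays alone.

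**Figure D1:**
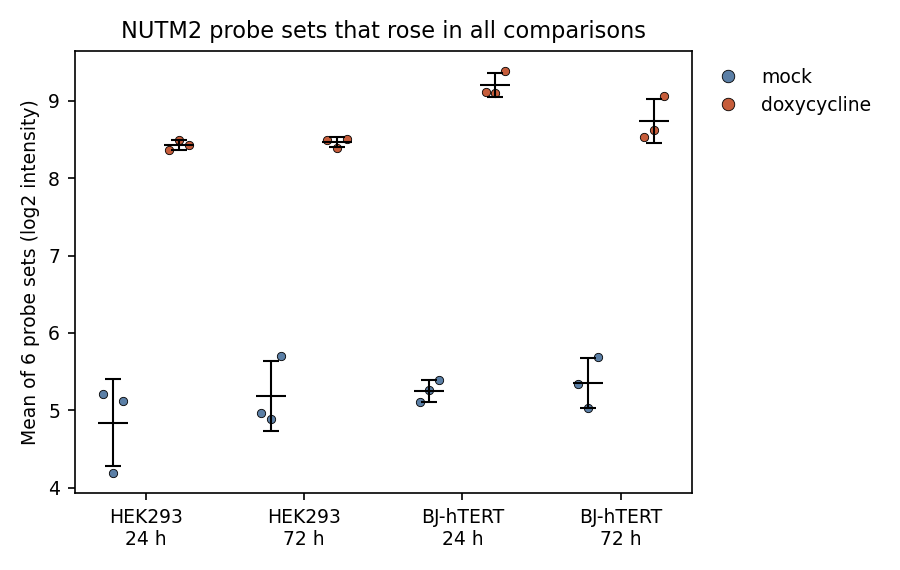
Mean log2 intensity of the 6 NUTM2 probe sets that rose in all 4 comparisons, by line, time and treatment; each point is 1 array and the bar is the group mean ± SD (n = 3). Every doxycycline array lies at 8.36 or above and every mock array at 5.70 or below.

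In HEK293 at 24 h, the comparison asks what the induced fusion changes early in a kidney line, and nearly all the change was upward. VSTM2B rose most, by 3.23 ± 0.25 log2 (9.40-fold, n = 3, adjusted p = 2.3e-07), from 3.01 in mock cells to 6.24. The neurotrophin receptor genes NGFR and NTRK3 rose by 2.08 ± 0.21 and 1.67 ± 0.16. ELFN1 rose by 1.88 ± 0.19, LRRTM1 by 1.76 ± 0.24, GABBR2 (a GABA-B receptor subunit) by 1.76 ± 0.17, PCDH1 by 1.69 ± 0.25 and PCDH10 by 1.45 ± 0.13. The homeobox gene NKX6-2 rose by 1.67 ± 0.29, the growth factor BMP6 by 1.49 ± 0.17 and the pseudogene FKBP1AP1 by 1.90 ± 0.28 (1 probe set). The 3 called falls were HNRNPH2 at -1.13 ± 0.24, LINC00853 at -0.85 ± 0.18 and DHX58 at -0.65 ± 0.14, and each lost its call with only these 6 arrays in the fit. The lower group means of LRRTM1 (log2 2.40), PCDH1 (2.30), FKBP1AP1 (2.27) and LINC00853 (2.36) lie below the filter value of 2.83, so the sizes of these changes are uncertain.

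Receptor and ERK pathway genes led the lists that rose in HEK293 at 24 h. Of 22 receptor tyrosine kinase and growth factor receptor genes, 3 rose and none fell (5 rose adjusted over the list alone), with NTRK3, NGFR and IGF1R (0.74 ± 0.10) called and a list mean of 0.41 (camera adjusted p = 5.9e-08). Of 26 ERK pathway output genes, 3 rose and none fell (6 rose adjusted over the list alone). They were the ETS factors ETV4 (0.80 ± 0.13) and ETV5 (1.15 ± 0.23) and the phosphatase DUSP4 (1.14 ± 0.20), and the list mean was 0.29 (adjusted p = 6.0e-06). Of 17 marker genes of clear cell sarcoma of the kidney and uterine stromal sarcoma, 2 rose (7 adjusted over the list alone), again NTRK3 and NGFR, while CCND1 (0.51 ± 0.14) and MEIS2 (0.52 ± 0.15) did not pass over all genes. Small shared shifts without a called member appeared in HOX genes (27 of 32 above 0, mean 0.23, adjusted p = 0.00039; 1 rose adjusted over the list alone) and in ribosome biogenesis and MYC target genes (17 of 20 above 0, mean 0.16, adjusted p = 0.0085; 0 adjusted over the list alone). Genes tied to matrix and movement rose singly: COL12A1 by 0.84 ± 0.12, the proteases ADAMTS5 by 1.23 ± 0.17 and ADAMTS9 by 1.06 ± 0.16, and the actin bundler FSCN1 by 1.12 ± 0.12.

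Over the 17329 genes tested, limma called 82 in HEK293 at 24 h, of which 79 rose and 3 fell, and 49 rose at least 2-fold. All 82 had their 3 doxycycline arrays apart from their 3 mock arrays, against 14% of all genes and 10% by chance. Genes were called on these same arrays, so the separation of called genes largely follows from the call and is not separate evidence. At unadjusted p under 0.05 there were 1484 genes, where 866 were expected by chance. All 5 called lists kept their calls with an estimated correlation, the highest adjusted p being 0.040. With only these 6 arrays in the fit the count was 22, and with the median of a gene's probe sets it was 35.

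In HEK293 at 72 h the question is what lasts or follows, and the ERK pathway stood out. ETV4 rose by 1.90 ± 0.13 log2 (3.73-fold, n = 3, adjusted p = 2.4e-08), ETV5 by 2.11 ± 0.23, the feedback inhibitor SPRY4 by 1.81 ± 0.18 and JUNB by 1.12 ± 0.12. VSTM2B rose by 3.47 ± 0.25 (11.1-fold), ELFN1 by 2.52 ± 0.19, NKX6-2 by 2.25 ± 0.29, the Notch ligand DNER by 2.19 ± 0.17, CLEC18A by 2.11 ± 0.39, GABBR2 by 1.93 ± 0.17, NTRK3 by 1.93 ± 0.16, LRRTM1 by 1.92 ± 0.24 and NGFR by 1.91 ± 0.21. The cyclin gene CCND1 rose by 1.15 ± 0.14, the cell death gene BIK by 1.21 ± 0.21 and LOXL2 by 0.96 ± 0.21. Falls were smaller. RAB27A fell by 1.01 ± 0.18 on the log2 scale, RIN2 by 1.00 ± 0.13, steroid sulfatase STS by 0.91 ± 0.11, ENPP5 by 0.86 ± 0.16, MDFIC by 0.77 ± 0.13, ID3 by 0.76 ± 0.14, IGFBP7 by 0.71 ± 0.13, PCDH18 by 0.68 ± 0.14, SEMA3C by 0.67 ± 0.14 and the protease PLAT by 0.58 ± 0.11. TRIM73 (-1.55 ± 0.37, 1 probe set), FAXDC2 (-0.96 ± 0.22), CTNNA3 (-0.89 ± 0.20), C2orf15 (-0.87 ± 0.20), FAM138E (-0.83 ± 0.20, 1 probe set), TP53I3 (-0.82 ± 0.18) and LIPH (-0.79 ± 0.19) also fell, and each of these 7 lost its call in at least 3 alternatives. CTNNA3 turned to 0.0452 when only brighter probe sets were averaged. The sizes of the changes of CLEC18A (mock mean log2 1.73), LRRTM1 (2.78), ETV5 (2.79), RIN2 (doxycycline mean 2.81) and CTNNA3 (2.47) are uncertain too, with a group mean below the filter value.

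Of the 26 ERK pathway output genes, 9 rose at 72 h in HEK293 and none fell (14 rose adjusted over the list alone), with a mean of 0.66 (camera adjusted p = 1.9e-20). Their mean level was 5.19 (SD 0.0436) in doxycycline arrays and 4.53 (SD 0.0599) in mock arrays. Receptor genes followed, with 5 of 22 up (7 adjusted over the list alone, mean 0.44, adjusted p = 2.2e-08), among them IGF1R (0.97 ± 0.10) and NTRK2 (0.91 ± 0.21). Of the 17 sarcoma markers 4 rose, NTRK3, NGFR, CCND1 and EGFR (0.66 ± 0.16; 6 rose adjusted over the list alone, mean 0.48, adjusted p = 9.5e-07). NTRK3, NGFR and EGFR also belong to the receptor list and CCND1 to the ERK list, so this call is not separate evidence. Of 32 HOX genes 3 rose, HOXD10 (0.64 ± 0.12), HOXB6 (0.99 ± 0.20) and HOXA11 (0.79 ± 0.18; 4 adjusted over the list alone, mean 0.22, adjusted p = 0.0006). Of 13 neural differentiation genes NEFL (0.99 ± 0.18) and NEFH (0.73 ± 0.17) rose (3 rose and 1 fell adjusted over the list alone, adjusted p = 0.026), and this list call was lost with an adjusted p = 0.072 with an estimated correlation. The lower lists had 0 called members over all genes or adjusted over the list alone: G2 and mitosis genes (mean -0.17, adjusted p = 0.00024) and cholesterol synthesis genes (mean -0.22, adjusted p = 0.00067). Both were lost, with adjusted p = 0.36 and adjusted p = 0.17 with an estimated correlation. At single genes, COL12A1 (1.25 ± 0.12), ADAMTS5 (1.22 ± 0.17), FSCN1 (1.11 ± 0.12) and CDH4 (0.84 ± 0.16) rose.

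The limma test called 210 genes in HEK293 at 72 h, 165 up and 45 down, with 89 up and 2 down at least 2-fold. All 210 had their 3 doxycycline arrays apart from their 3 mock arrays, against 17.6% of all genes and 10% by chance. This separation again largely follows from the call. At unadjusted p under 0.05 there were 2016 genes. The count was 79 with only these 6 arrays in the fit and 88 with the median of probe sets.

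**Figure D2:**
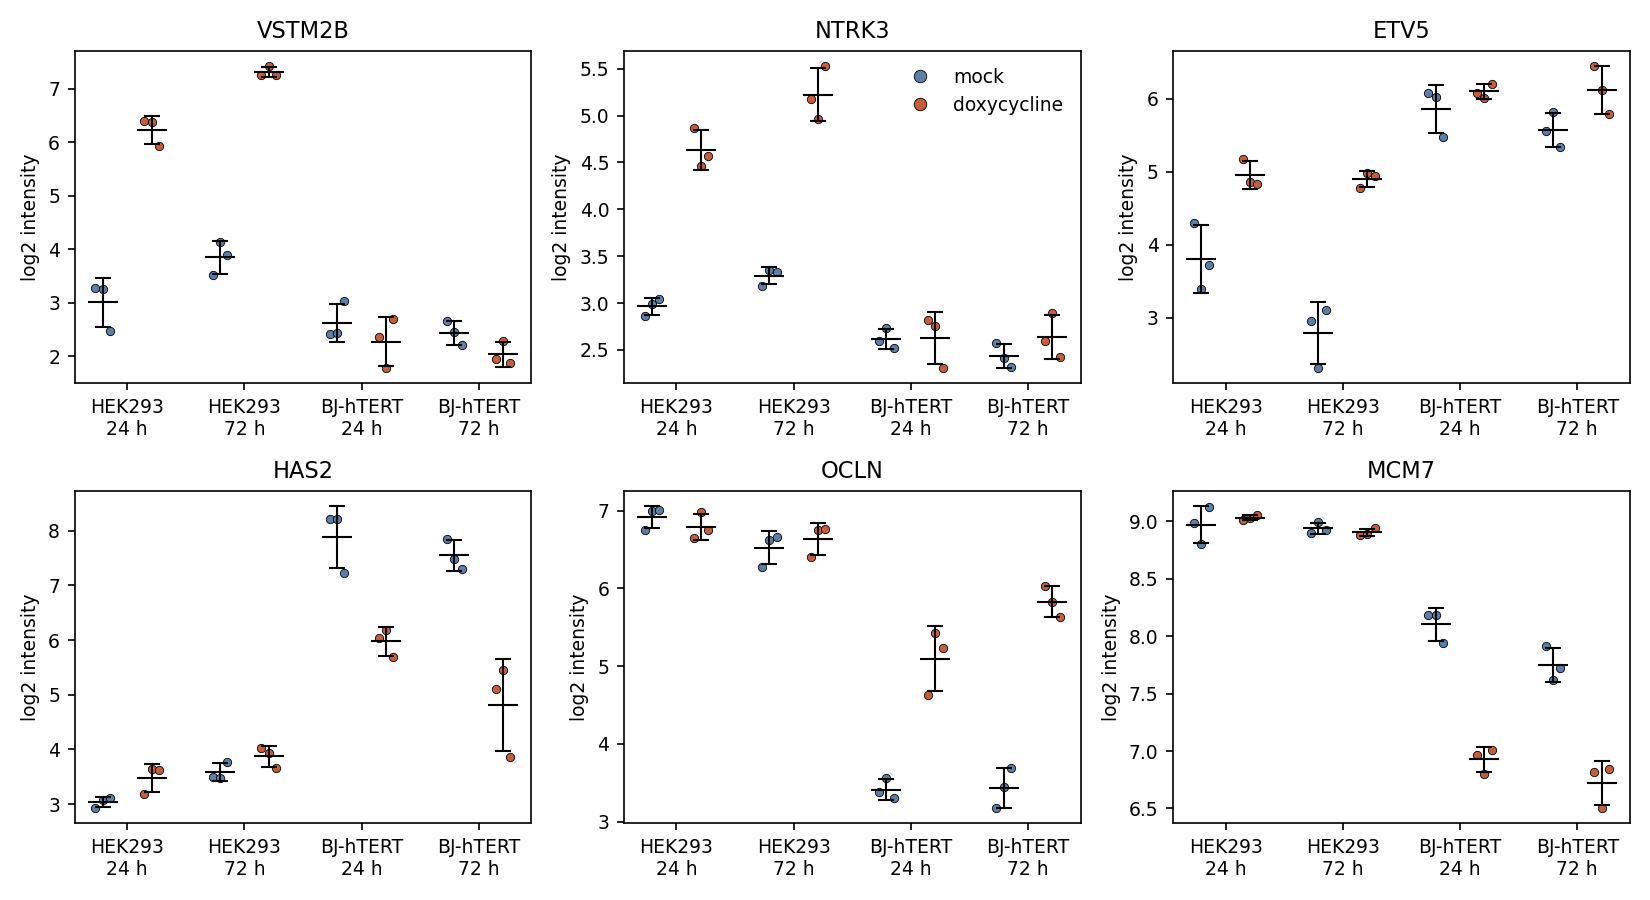
Log2 expression of VSTM2B, NTRK3, ETV5, HAS2, OCLN and MCM7 in each group; points are arrays and bars are group means ± SD (n = 3). VSTM2B rises with doxycycline in HEK293 (3.01 to 6.24 at 24 h), while HAS2 falls in BJ-hTERT (7.88 to 5.97 at 24 h).

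In BJ-hTERT at 24 h, after the same induction in a fibroblast line, genes of dividing cells fell together. Called genes as a whole rose about as often as they fell (774 and 760). All 32 G2 and mitosis genes fell, among them BUB1B by 1.38 ± 0.10 log2 (n = 3, adjusted p = 3.4e-08), CDCA8 by 1.41 ± 0.11, the cyclin CCNA2 by 1.24 ± 0.10 and the kinase PLK1 by 1.17 ± 0.09. Of 29 replication and S phase genes 28 fell, with MCM3 down by 1.14 ± 0.09, MCM7 by 1.18 ± 0.12, thymidylate synthase TYMS by 1.11 ± 0.11 and CDC25A by 1.06 ± 0.10. Of 17 replication-dependent histone genes 13 fell, and histone genes filled most of the largest falls: HIST1H2AK (now H2AC15) fell by 2.03 ± 0.21, HIST1H2BI by 1.97 ± 0.27, HIST1H2AJ (H2AC14) by 1.90 ± 0.41, HIST1H2BB (H2BC3) by 1.89 ± 0.26, HIST1H2AE (H2AC8) by 1.69 ± 0.11 and HIST1H4D (H4C4) by 1.62 ± 0.10. LMNB1, encoding lamin B1, fell by 1.10 ± 0.11 and the histone methyltransferase EZH2 by 1.10 ± 0.16. HAS2, the hyaluronan synthase, fell by 1.91 ± 0.31 (adjusted p = 0.00023). Genes that rose included UST by 1.79 ± 0.14, FAM65B (now RIPOR2) by 1.77 ± 0.24, the muscle and neural factor MEF2C by 1.74 ± 0.20, the tight junction gene OCLN by 1.69 ± 0.19, the stress factor ATF3 by 1.69 ± 0.28, HSPB3 by 1.87 ± 0.26, TCP11L2 by 1.74 ± 0.19, ABCB4 by 1.73 ± 0.23 and FAXDC2 by 1.70 ± 0.22. GOLGA8B, up by 2.86 ± 0.46, and GABRE, down by 2.42 ± 0.72, each rest on 1 probe set whose lower group mean, log2 0.88 in mock cells for GOLGA8B and 0.81 in doxycycline cells for GABRE, lies below the filter value of 2.83, so the sizes of both changes are uncertain, as are those of ATF3 (mock mean 2.60) and HSPB3 (2.72).

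The list means in BJ-hTERT at 24 h were -1.12 for G2 and mitosis genes (camera adjusted p = 1.3e-54), -0.98 for replication genes (8.2e-44) and -1.13 for histone genes (1.1e-22). Adjusted over the list alone, 32, 29 and 15 members fell. The mean level of the G2 and mitosis list was 7.37 (SD 0.153) in doxycycline arrays and 8.50 (SD 0.0701) in mock arrays. Ribosome biogenesis and MYC target genes fell less, 5 of 20 with FBL down by 0.61 ± 0.11 and NOP58 by 0.57 ± 0.12 (5 adjusted over the list alone, mean -0.29, adjusted p = 0.00095). Of 34 ATF4 and amino acid response genes 3 rose and 8 fell, SLC7A11 by 0.97 ± 0.21 and PSAT1 by 0.64 ± 0.13 (3 and 13 adjusted over the list alone, mean -0.26, adjusted p = 5.7e-05). Of 32 HOX genes 6 rose, HOXA11 by 1.37 ± 0.18, HOXA13 by 1.29 ± 0.19 and HOXA5 by 1.21 ± 0.15 (6 adjusted over the list alone, adjusted p = 0.019). The ATF4 and HOX calls were lost, with adjusted p = 0.090 and adjusted p = 0.11 with an estimated correlation, and the other 4 were kept. List p-values of the doxycycline comparisons use the preset correlation unless stated, which can give far smaller values than an estimated one. For G2 and mitosis genes over time in mock BJ-hTERT, camera adjusted p was 3.2e-22 with the preset and 0.0065 with the estimated correlation. The ERK list missed the threshold (adjusted p = 0.051) with members going both ways: EPHA4 (0.91 ± 0.14), SPRY1 (0.92 ± 0.14) and ETV4 (0.82 ± 0.13) rose and FOSL1 (-1.13 ± 0.17) fell, and 10 rose and 3 fell adjusted over the list alone. Single genes of adhesion and signalling changed too. ITGB8 (1.31 ± 0.17, mock mean 2.65, below the filter value), ITGA11 (1.00 ± 0.15), JUP (1.11 ± 0.19), TWIST1 (1.53 ± 0.32), the Hedgehog receptor gene PTCH1 (1.31 ± 0.16), JAG1 (0.94 ± 0.15) and NDRG1 (1.42 ± 0.16) rose, while ANKRD1 (-1.35 ± 0.22), F3 (-1.27 ± 0.23), SNAI2 (-0.69 ± 0.18) and MYLK (-0.75 ± 0.15) fell.

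The limma test called 1534 genes in BJ-hTERT at 24 h, 774 up and 760 down, with 103 up and 223 down at least 2-fold. Of these, 1508 had their 3 doxycycline arrays apart from their 3 mock arrays, against 25.8% of all genes and 10% by chance. This separation again largely follows from the call. At unadjusted p under 0.05 there were 3673 genes. The count was 697 with only these 6 arrays in the fit and 903 with the median of probe sets, and the GABRE call was lost without a filter.

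In BJ-hTERT at 72 h, replication, mitosis and histone genes were again below mock cells. HAS2 fell by 2.74 ± 0.31 log2 (n = 3, adjusted p = 8.0e-06), from 7.55 in mock cells to 4.81. The chemokines CXCL12 and CCL2 fell by 1.66 ± 0.19 and 1.63 ± 0.23, TNFRSF11B, which encodes osteoprotegerin, by 1.62 ± 0.26, TNFAIP3 by 1.32 ± 0.19 and PTGS2 by 0.74 ± 0.17. The contractile genes MYLK and ACTA2 fell by 1.13 ± 0.15 and 0.84 ± 0.21, tenascin TNC by 1.07 ± 0.14, neuropilin NRP1 by 0.95 ± 0.12, SEMA3A by 0.89 ± 0.15, the urokinase gene PLAU by 0.87 ± 0.19 and ITGA8 by 0.99 ± 0.20. OCLN rose by 2.39 ± 0.19 (5.26-fold, adjusted p = 2.3e-07), SERPINI1 by 1.98 ± 0.20, ABCB4 by 1.95 ± 0.23, ACPP (now ACP3) by 1.79 ± 0.20, ANKRD29 by 1.78 ± 0.27 and ATF3 by 1.75 ± 0.28. Matrix and adhesion genes rose as well as fell, COL11A1 up by 1.25 ± 0.16, COL4A1 by 0.62 ± 0.09, ITGA11 by 1.13 ± 0.15, ITGB8 by 1.04 ± 0.17, ADAMTS5 by 1.00 ± 0.17 and CTGF (now CCN2) by 1.07 ± 0.17. Other large falls were ALG10 by 1.72 ± 0.21, LINC00707 by 1.77 ± 0.42, FAM196B (now INSYN2B) by 1.61 ± 0.27 and RPL29P19 by 1.60 ± 0.23. GABRE rose by 2.53 ± 0.72 at 72 h after its fall at 24 h, but the difference between times (4.95) missed the threshold (adjusted p = 0.10), and its mock mean of log2 1.83 lies below the filter value as well.

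Of 32 G2 and mitosis genes 30 fell in BJ-hTERT at 72 h (32 adjusted over the list alone, mean -0.93, camera adjusted p = 1.2e-43), with AURKB at -1.18 ± 0.12 and PLK1 at -1.05 ± 0.09. Of 29 replication genes 26 fell (28 fell and 1 rose adjusted over the list alone, mean -0.76, adjusted p = 4.4e-30), with POLA1 at -1.18 ± 0.11. Of 17 histone genes 12 fell (14 adjusted over the list alone, mean -0.92, adjusted p = 1.4e-15), with HIST1H3B (now H3C2) at -1.50 ± 0.13. The 1 histone gene that rose was HIST1H4H (now H4C8, log2 1.09), chosen after its values were seen. Of 20 ribosome biogenesis genes 4 fell (4 adjusted over the list alone, mean -0.28, adjusted p = 9.7e-05), FBL by 0.86 ± 0.11. Of 14 chemokine and cytokine genes 4 fell and 1 rose (6 and 1 adjusted over the list alone, mean -0.44, adjusted p = 0.011). Of 23 cytosolic ribosomal protein genes RPL11 (-0.59 ± 0.12) and RPL10A (-0.37 ± 0.11) fell (8 adjusted over the list alone, mean -0.25, adjusted p = 0.0014). Of 32 HOX genes 6 rose, HOXA5 by 1.51 ± 0.15 (6 adjusted over the list alone, mean 0.23, adjusted p = 0.0085). These last 3 calls were lost: chemokines with adjusted p = 0.085, ribosomal proteins with adjusted p = 0.077 and HOX genes with adjusted p = 0.082 with an estimated correlation. Of 33 extracellular matrix genes 6 rose and 8 fell, over all genes and adjusted over the list alone, and the list was not called (adjusted p = 0.97).

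The limma test called 1494 genes in BJ-hTERT at 72 h, 699 up and 795 down, with 98 up and 145 down at least 2-fold. Of these, 1475 had their 3 doxycycline arrays apart from their 3 mock arrays, against 25.1% of all genes and 10% by chance. This separation again largely follows from the call. At unadjusted p under 0.05 there were 3712 genes. The count was 551 with only these 6 arrays in the fit and 826 with the median of probe sets; the calls of GABRE, HIST1H2BM (now H2BC14, -1.58 ± 0.45) and PCDHGC5 (-1.55 ± 0.45, with a doxycycline mean below the filter value) were each lost in at least 2 alternatives.

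**Figure D3:**
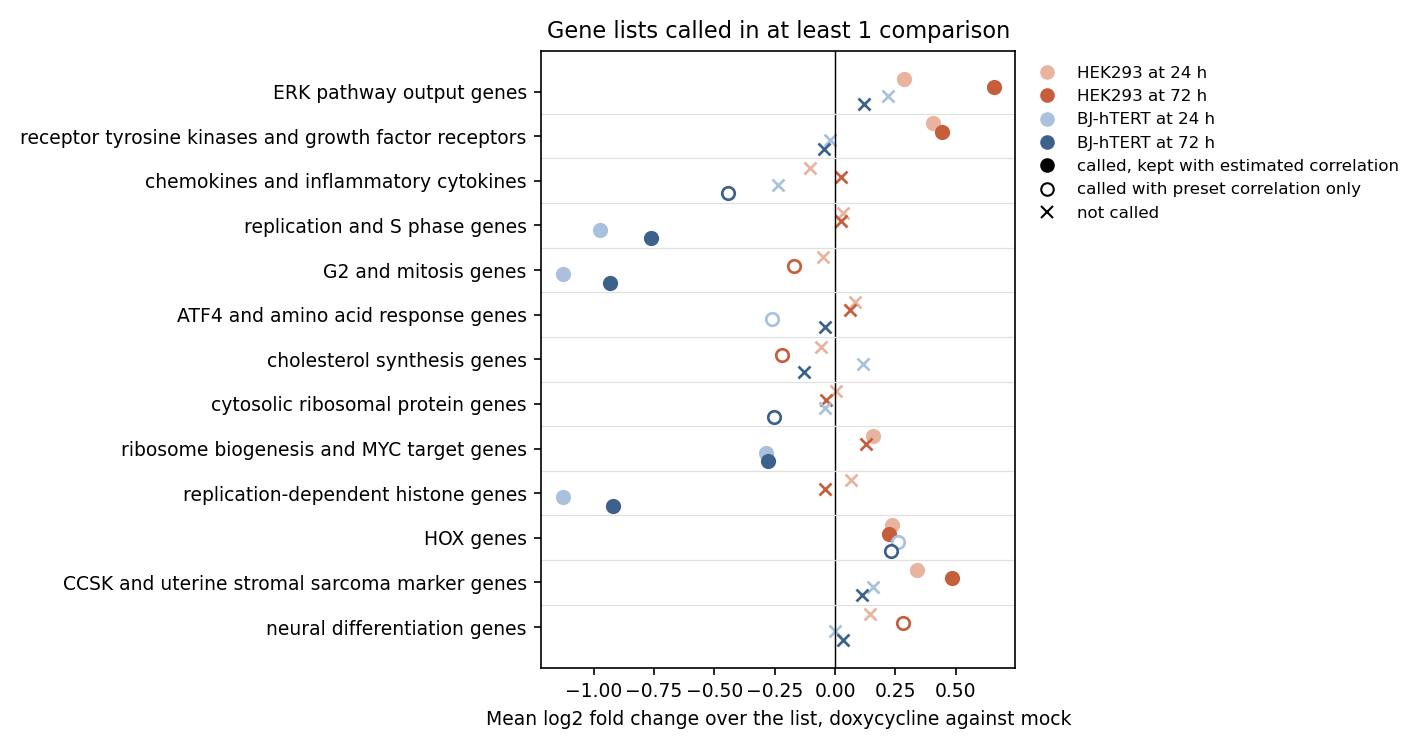
Mean log2 change with doxycycline of 13 gene lists in the 4 comparisons; filled points were called with the preset and the estimated correlation, open points with the preset correlation only, and crosses were not called. ERK and receptor genes lie above 0 in HEK293 (0.66 and 0.44 at 72 h), and replication, mitosis and histone genes lie near -1 in BJ-hTERT.

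Over the 4 comparisons 25 of 184 list results were called, 17 also with an estimated correlation. Mean, median and test differed in sign for 25 list results, 0 of them called; for replication-dependent histone genes in HEK293 at 24 h the mean was 0.06, the median -0.02 and the camera direction down. No called list changed direction or lost its call under 4 other scalings. The 14-3-3 family, the group to which YWHAE belongs, had 6 tested members and 0 called by limma in any comparison, with a lowest list adjusted p of 0.37.

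Whether the doxycycline effect differed between 24 and 72 h was tested directly within each line. In HEK293 the effect was larger at 72 h for SPRY4 (difference 1.62 ± 0.25 log2, limma adjusted p = 0.022) and ETV4 (1.10 ± 0.18, 0.036) and lower for RIN2 (-1.22 ± 0.19, 0.022), the 3 genes called. SPRY4 fell by 1.29 log2 over time in mock cells and did not fall in doxycycline cells (a change of 0.33), and ETV4 fell by 0.93 in mock cells against a change of 0.16. In BJ-hTERT the only gene called was TRO, with a difference of -1.33 ± 0.21 (adjusted p = 0.045) between a rise of 0.71 at 24 h and a fall of 0.62 at 72 h. At unadjusted p under 0.05 there were 1138 genes in HEK293 and 1535 in BJ-hTERT. All 4 calls were lost when the arrays of 1 line were fitted alone. As a list, ERK pathway genes differed by 0.37 in HEK293 (adjusted p = 0.00025 with an estimated correlation). Replication genes differed by 0.21 in BJ-hTERT (adjusted p = 0.0499 with an estimated correlation).

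**Figure D4:**
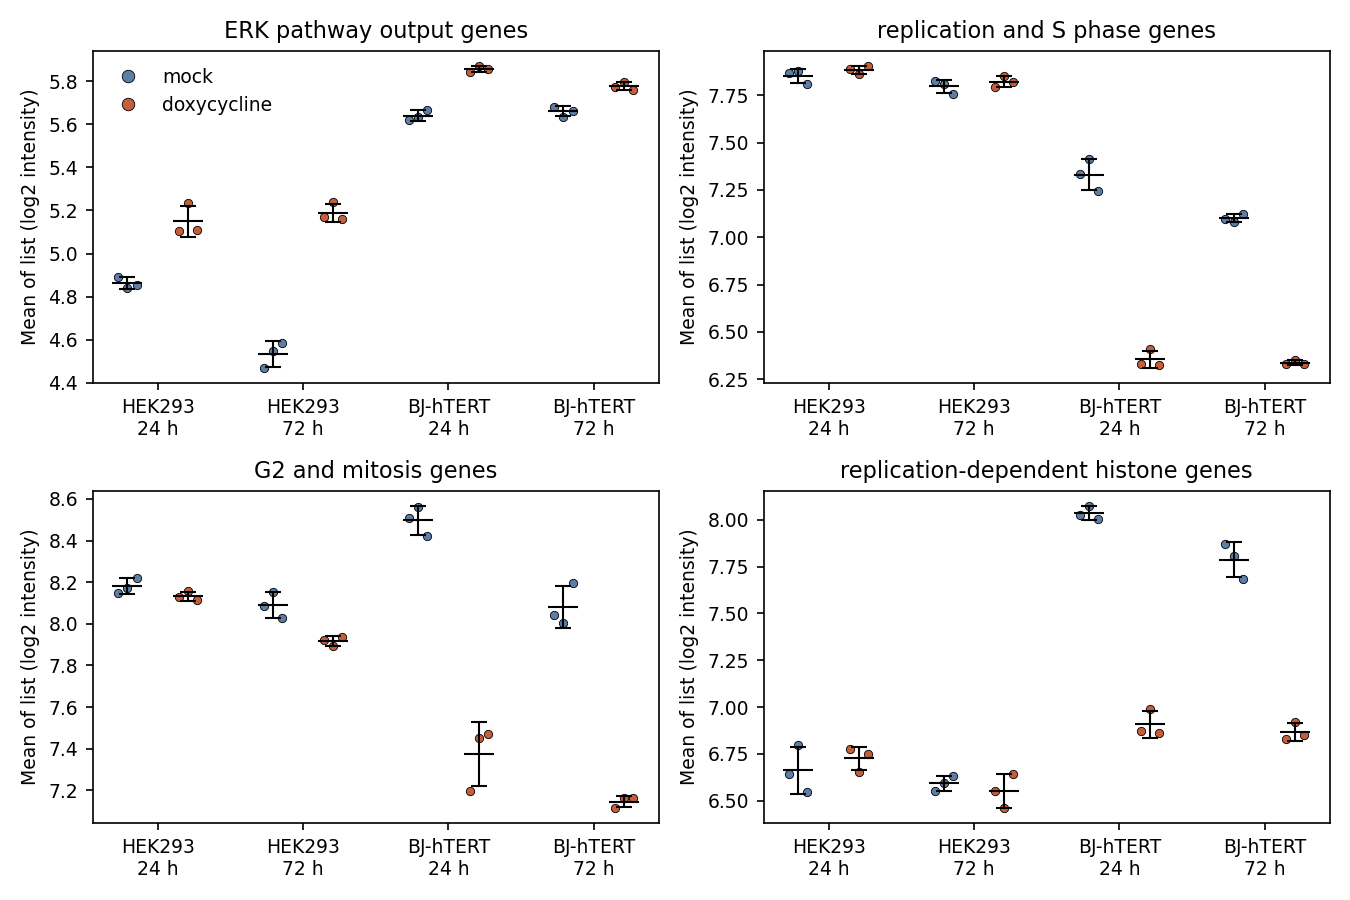
Mean log2 expression of the ERK pathway output, replication, G2 and mitosis, and histone gene lists; points are arrays and bars are group means ± SD (n = 3). ERK genes in HEK293 mock cells go from 4.86 at 24 h to 4.53 at 72 h, while doxycycline cells stay at 5.15 and 5.19; G2 and mitosis genes in BJ-hTERT stand at 7.37 against 8.50 in mock cells at 24 h.

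The lines shared few responses beyond NUTM2. At 24 h, 7 genes rose in both: ETV4 (0.80 ± 0.13 in HEK293 and 0.82 ± 0.13 in BJ-hTERT), FSCN1 (1.12 ± 0.12 and 0.42 ± 0.12), HDAC5 (1.04 ± 0.21 and 1.01 ± 0.21), IGDCC3 (1.01 ± 0.17 and 0.56 ± 0.17, with a BJ-hTERT mock mean below the filter value), KLHL29 (0.76 ± 0.15 and 0.50 ± 0.15), SOCS2 (0.73 ± 0.16 and 0.61 ± 0.16) and NUTM2B. At 72 h, 16 genes rose in both and 3 fell in both. The risers included NTNG2 (1.41 ± 0.27 and 1.34 ± 0.27), NUTM2G (1.33 ± 0.29 and 1.43 ± 0.29), ADAMTS5 (1.22 ± 0.17 and 1.00 ± 0.17), PDE4A (1.24 ± 0.18 and 0.97 ± 0.18), NR4A3 (0.93 ± 0.15 and 0.82 ± 0.15), RFX2 (1.29 ± 0.20 and 0.67 ± 0.20), HOXA11 (0.79 ± 0.18 and 0.93 ± 0.18) and again ETV4. The fallers were PCDH18 (-0.68 ± 0.14 and -0.67 ± 0.14), PLAT (-0.58 and -0.44) and COX20, which was chosen after its values were seen. In 17 genes the calls at 72 h went opposite ways, among them FOSL1 (1.22 in HEK293 and -1.20 in BJ-hTERT), GABBR2 (1.93 and -0.65), PCDH10 (1.58 and -0.43) and STS (-0.91 and 0.48).

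By chance 3.53 shared rises were expected at 24 h (one-sided Fisher's exact p = 0.063, adjusted over 8 overlap tests 0.10) and 6.66 at 72 h (p = 0.0011, adjusted 0.0021). The shared rises counted include the induced NUTM2B at both times and NUTM2G at 72 h, and the overlap without them was not tested. For shared falls at 72 h 2.06 were expected (one-sided Fisher's exact p = 0.34, adjusted 0.45), and no gene was called down in both lines at 24 h, where 3 genes were called down in HEK293. Across genes, which are not independent replicates, the log2 changes of the lines had r = -0.0096 at 24 h and -0.016 at 72 h. Within a line the times shared far more. In HEK293 58 genes rose at both times where 0.752 were expected (r = 0.233 across genes), and in BJ-hTERT 328 rose and 434 fell where 31.2 and 34.9 were expected (r = 0.479). The 7 shared genes at 24 h became 1 with the median of probe sets, 0 with only the groups of a comparison in the fit and 3 at the lowest without 1 array. The 19 at 72 h became 6, 5 and 12 in the same order, and whether those smaller overlaps exceed chance was not tested.

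**Figure D5:**
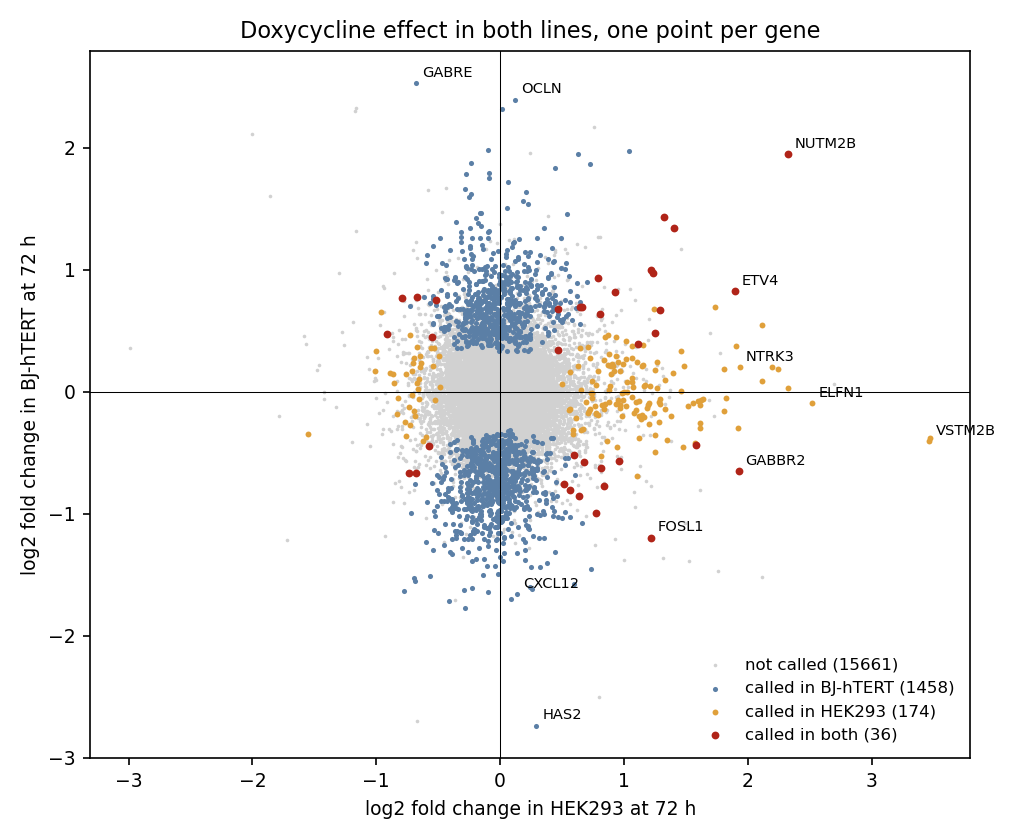
Log2 change with doxycycline at 72 h in HEK293 (horizontal axis) against BJ-hTERT (vertical axis); each point is a gene, coloured by where it was called. Calls in BJ-hTERT only numbered 1458, in HEK293 only 174 and in both 36, and VSTM2B and HAS2 lie along different axes.

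Tested directly, the doxycycline effect differed between the lines for 821 genes at 24 h and 914 at 72 h by limma. Among named genes VSTM2B had the largest difference (BJ-hTERT minus HEK293 -3.58 ± 0.35 log2, adjusted p = 9.4e-06, and -3.87 ± 0.35 at 72 h, 2.9e-06). At 24 h HIST1H3G (now H3C8, -2.78 ± 0.45), PCDHGC5 (-2.47 ± 0.63), HAS2 (-2.35 ± 0.43) and FAXDC2 (2.17 ± 0.31) came next. At 72 h they were HAS2 (-3.03 ± 0.43), ELFN1 (-2.61 ± 0.27), GABBR2 (-2.58 ± 0.24) and FOSL1 (-2.42 ± 0.24). The sizes for VSTM2B, HIST1H3G and PCDHGC5 are uncertain, since each has a group mean below the filter value. The 24 h effect was higher in BJ-hTERT for 272 genes and lower for 549; at 72 h these were 420 and 494, a split that median centring of the arrays turned to 532 and 398. As lists, replication genes differed by -1.01 at 24 h and -0.79 at 72 h, G2 and mitosis genes by -1.08 and -0.76, histone genes by -1.19 and -0.88 and ribosome biogenesis genes by -0.44 and -0.41, with adjusted p of at most 0.0070 with an estimated correlation. At 72 h the ERK list differed by -0.54 (0.0017) and the receptor list by -0.49 (0.045). The ERK list mean was also higher with doxycycline in BJ-hTERT, 5.86 against 5.64 at 24 h and 5.78 against 5.66 at 72 h. It was not called there at either time. In HEK293 mock cells it fell from 4.86 at 24 h to 4.53 at 72 h, which enters the 72 h difference. The 914 moved to 383 with the median of probe sets, and the 821 to 377.

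Averaged over both lines and times, limma called 1745 genes, 943 with a higher and 802 with a lower mean of the 4 effects, and 3848 genes had an unadjusted p under 0.05. Most mean effects were small, with a median size of 0.37 log2 among called genes and 18 genes at 2-fold or more. With a minimum fold of 1.5 the count was 217.

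Mock cells differed between 24 and 72 h in both lines. Harvest or array batch was not separated from time in culture. In HEK293, 47 genes rose and 17 fell between 24 and 72 h, and the falls included the ERK outputs SPRY4 (-1.29 ± 0.18, adjusted p = 0.0020) and ETV4 (-0.93 ± 0.13), with HNRNPH2 (-1.39 ± 0.24, 1 probe set), FOLR2 (-1.04 ± 0.22) and ZFX (-0.92 ± 0.17). LINC00505 (now FAAHP1, 1.53 ± 0.29, 1 probe set), STC1 (1.41 ± 0.19), FKBP1AP1 (1.38 ± 0.28), FAXDC2 (1.38 ± 0.22) and RRAS (1.25 ± 0.21) rose. FKBP1AP1 rests on 1 probe set with a 24 h mean below the filter value. HNRNPH2 and FKBP1AP1 moved the same way with doxycycline at 24 h, a comparison that uses the same 24 h mock arrays. In BJ-hTERT, 201 rose and 120 fell. Median centring of the arrays made these 30 up and 29 down in HEK293 and 164 and 155 in BJ-hTERT, and without 1 array the totals of 64 and 321 were as low as 8 and 96. Sterol and lipid genes rose, INSIG1 by 1.77 ± 0.21 and SCD by 1.54 ± 0.17, with CPA4 (1.62 ± 0.23), FAXDC2 (1.57 ± 0.22) and SEMA3D (1.56 ± 0.20). ANKRD1 fell by 1.88 ± 0.22, MMP3 by 1.31 ± 0.22, TFPI2 by 1.17 ± 0.20 and SLC7A11 by 1.16 ± 0.21, and ISY1 (-2.07 ± 0.53) rests on 2 probe sets. The sizes for FOLR2 and ISY1 are uncertain, with 72 h means below the filter value. Doxycycline cells were therefore compared only with mock cells of the same time. With only the 6 mock arrays of a line in the fit, limma called 0 genes in either line; in the fit of all arrays 2162 and 2516 genes had an unadjusted p under 0.05.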

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

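The results here are differences of the doxycycline effect between times or lines, and changes in probe sets that the gene values leave out. The tests against normalisation, a doxycycline effect common to both lines, transgene reading, transgene position, a fall in mock cells and chance beside the mean doxycycline effect were chosen after the results were seen, as were the list tests on differences. The test of an older or denser culture and the other splits of the arrays were planned.

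The doxycycline effect on genes of dividing cells was lower in BJ-hTERT than in HEK293. The difference between lines (BJ-hTERT minus HEK293) was -1.01 log2 at 24 h and -0.79 at 72 h as a mean over replication genes, -1.08 and -0.76 over G2 and mitosis genes, -1.19 and -0.88 over histone genes, and -0.44 and -0.41 over ribosome biogenesis and MYC target genes. These 8 were picked out because the lines' effects differed in a direct test, as did the ERK list at 72 h (-0.54) and the receptor list at 72 h (-0.49). Over time the effect differed for the ERK list in HEK293 (0.37) and, just past the threshold, for the replication list in BJ-hTERT (0.21).

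The 78 replication, mitosis and histone genes fell in BJ-hTERT, with a median of -1.11 at 24 h and -0.94 at 72 h. Over 4 scalings and both times the median nearest 0 was -0.91. Those scalings shifted the median change over genes by only -0.058 to 0.031 log2, so they could not have removed the fall. Normalisation before deposit was not tested. A doxycycline effect common to both lines is argued against as the cause of the fall. The same genes had a median of -0.0102 in HEK293 at 24 h, with 40 of 78 below 0, and of -0.07 at 72 h, with 52 of 78 below 0. An effect of doxycycline itself in this line alone stays open, because no fusion-free line was treated. An older or denser culture in the doxycycline wells cannot be told apart from the fusion. The 201 genes that rose over time in mock BJ-hTERT (median 0.76) had a median change with doxycycline of 0.34 at 24 h (95% interval 0.28 to 0.40) and of -0.15 at 72 h. The 107 that fell over time (median -0.62) changed with doxycycline by nearly as much at 24 h (-0.55). All of these 24 h values share the 24 h mock arrays with the change over time, which draws them toward it. The 72 h value shares the 72 h mock arrays, which draws it the other way. The 78 genes themselves changed over time in mock cells by a median of -0.33, less than with doxycycline, but mock cells older or denser than at 72 h were not measured.

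VSTM2B rose in HEK293 alone, with line differences of -3.58 at 24 h and -3.87 at 72 h that were past the threshold of a direct test. Probe sets that read the induced transgene would have risen in BJ-hTERT as well, where the upper 95% bound of the change was 0.16 at most and NUTM2 probe sets did rise. Insertion of the transgene beside the gene in HEK293 may explain the rise and stays open: the 6 nearest tested protein-coding genes had 0 calls and a highest upper bound of 0.80, below the VSTM2B change, but an insertion can act on 1 gene only. A response of HEK293 cells to the fusion stays open as the biological explanation. Of the 6 VSTM2B probe sets, 4 rose at each time and all 6 were above 0.

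The larger ERK effect at 72 h in HEK293 came with the single genes SPRY4 (1.62) and ETV4 (1.10), picked out with RIN2 (-1.22) because the effect differed between times. Over 4 scalings the lowest mean difference between times was 0.36. Those scalings shifted the median change over genes by only -0.058 to 0.031 log2, so they could not decide on normalisation before deposit. The difference between times is by construction the change in doxycycline cells minus that in mock cells. A fall in mock cells that doxycycline cells did not share therefore describes the difference and does not explain it. The ERK list mean fell by 0.33 in mock cells between 24 and 72 h (95% interval -0.40 to -0.26) and changed by 0.0396 in doxycycline cells (-0.03 to 0.11). RIN2 rose by 1.23 in mock cells and changed by 0.01 in doxycycline cells.

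In all, 3 genes in HEK293 and 1 gene in BJ-hTERT, TRO (-1.33), had an effect that differed between times. Among 100 splits of the arrays 7 gave a count as large as the 3 in HEK293, the real one included, with 24 as the highest of the others. In BJ-hTERT 29 of 100 splits gave a count as large as 1, and the highest of the others called 533 genes. These splits do not test chance here. A split that calls several times the real count points to structure in the samples, and that structure was the doxycycline effect itself, which enters the difference when labels are exchanged unequally at the 2 times. Among the splits of 1 line alone the highest other counts were 41 in HEK293 and 679 in BJ-hTERT, and they fell to 3 and 4 once the mean doxycycline effect of the line was removed. With it removed, 2 of 77 splits gave as many as the 3 genes in HEK293, the real one included. Chance is not excluded there, since another split tied the count in a test chosen after the result was seen. All 3 calls were also lost without any 1 of 9 arrays. In BJ-hTERT 14 of 78 gave as many as 1, and chance is not excluded.

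Between lines, 821 genes at 24 h and 914 at 72 h differed in a direct test. Among splits of the arrays, 1 of 99 and 1 of 100 gave as many, the real ones, and the highest other counts were 46 and 8. These splits exchange labels within each line and so break up the doxycycline effect in both. They ask whether there is any effect, not whether it differs between lines, so they do not exclude chance for the difference. At 24 h the named genes were, besides VSTM2B, HIST1H3G (-2.78), PCDHGC5 (-2.47), HAS2 (-2.35) and FAXDC2 (2.17). At 72 h they were HAS2 (-3.03), ELFN1 (-2.61), GABBR2 (-2.58) and FOSL1 (-2.42).

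Signals outside the gene values were seen in probe sets not used for genes, each above the mock arrays or below them at adjusted p under 0.05. Of 77428 probe sets not listed with a gene, 11 were called in HEK293 at 24 h, 22 in HEK293 at 72 h, 133 in BJ-hTERT at 24 h and 76 in BJ-hTERT at 72 h. Of 17460 probe sets with several gene symbols, 11, 18, 134 and 79 were called in the same order, and 7 of these rose in all 4 comparisons, all naming NUTM2 genes.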

How the results depend on the processing

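The main choices and all alternatives but 3 were fixed before the data were examined. The exceptions, chosen after seeing the data, are counting copied probe sets once, adding probe sets with several names of 1 gene, and leaving out arrays for the NUTM2 probe sets; the first 2 moved no count by more than 1.5 times. The counts below moved by more than that from the reported 82 and 210 (HEK293 at 24 and 72 h), 1534 and 1494 (BJ-hTERT), 3 and 1 (time differences in HEK293 and BJ-hTERT), 821 and 914 (line differences at 24 and 72 h), 1745 (mean effect), 64 and 321 (mock time in HEK293 and BJ-hTERT), 7 and 19 (shared genes at 24 and 72 h), 25 lists and 6 NUTM2 probe sets. The cause was not tested unless stated.

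Scaling moved few. The BJ-hTERT time difference became 0 by limma under median centring, quantile normalisation over all arrays or within lines, and cyclic loess, and the 24 h overlap became 4 under median centring. Median centring also turned the split of the 72 h line difference to 532 up and 398 down (57.2% up against 46%). Mock time became 30 up and 29 down in HEK293 (50.8% against 73.4%) and 164 and 155 in BJ-hTERT (51.4% against 62.6%). With no filter the BJ-hTERT time difference was 0, HEK293 mock time 31 and the 24 h overlap 4. With the filter at the 60th percentile they were 4, 136 and 14, where fewer genes were tested.

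With the median of a gene's probe sets the counts were 35 and 88 in HEK293, 903 and 826 in BJ-hTERT, 0 and 2 for time, 377 and 383 for line, 1015 for the mean effect, 11 and 57 for mock time, and 1 and 6 for overlap. With only brighter probe sets in the mean they were 13 for BJ-hTERT time, 1250 and 1433 for line, 216 and 592 for mock time, and 20 and 46 for overlap. There the changes of CTNNA3 in HEK293 at 72 h (0.0452 in place of -0.89) and GLI1 in BJ-hTERT at 72 h (0.0703 in place of -0.80) reversed, both without a call. With 1 test per probe set they were 125 for HEK293 at 72 h, 15 and 18 for time, 396 and 190 for line, 79 for BJ-hTERT mock time, 7 for the 72 h overlap and 47 lists.

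Fits with fewer arrays, which leave fewer degrees of freedom, lowered counts. With 1 line alone they were 0 and 0 for time, 2 and 78 for mock time, 4 and 11 for overlap, and 0 NUTM2 probe sets. With only the groups of a comparison they were 22 and 79 in HEK293, 697 and 551 in BJ-hTERT, 0 and 0 for time, 500 and 560 for line, 0 and 0 for mock time, 0 and 5 for overlap, and 0 NUTM2 probe sets. An intensity trend with robust eBayes gave 1 and 4 for time, 147 for HEK293 mock time and 13 for the 24 h overlap, and array weights gave 12 for the 24 h overlap. Replicate numbers do not pair samples: residuals of equal numbers correlated at -0.0252 to 0.0860. As a block within line and time they gave 0 and 0 for time, 592 for line at 72 h, 12 for the 72 h overlap and 0 NUTM2 probe sets, and could give no value for mock time in either line; as a block within line they gave 0 for HEK293 time. Fry called 55 lists and camera with an estimated correlation 17. A minimum fold of 1.5 gave 217 for the mean effect and 4 for the 24 h overlap. At adjusted p under 0.01 the counts were 54, 113, 837 and 797, then 0 and 0 for time, 373 and 378 for line, 1021 for the mean effect, 8 and 83 for mock time, and 2 and 7 for overlap, by construction of the threshold.

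Leaving out 1 array at a time, which leaves 2 arrays in its group, gave 62 to 75 and 143 to 178 genes in HEK293, 1132 to 1295 and 1080 to 1224 in BJ-hTERT, 591 to 766 and 651 to 751 for line, 1587 to 1722 for the mean effect and 24 to 33 lists. HEK293 time ran from 0 to 3 and was 0 without any of 9 arrays (mock 24 h replicates 1 and 3, doxycycline 24 h replicates 1 and 3, mock 72 h replicates 1 and 3, and all 3 doxycycline 72 h replicates). BJ-hTERT time ran from 0 to 3, being 0 without any mock 24 h replicate, doxycycline 24 h replicate 3, mock 72 h replicates 2 and 3, or doxycycline 72 h replicates 2 and 3, and 3 without doxycycline 72 h replicate 1. HEK293 mock time ran from 8 to 79: 17 and 24 without mock 24 h replicates 2 and 3, 23 and 8 without mock 72 h replicates 1 and 3. BJ-hTERT mock time ran from 96 to 249: 155 and 100 without mock 24 h replicates 1 and 2, 120, 96 and 210 without mock 72 h replicates 1, 2 and 3. The 24 h overlap ran from 3 to 9: 4 without HEK293 mock replicate 2, HEK293 doxycycline replicate 1 or BJ-hTERT mock replicate 1, and 3 without HEK293 doxycycline replicate 2 or BJ-hTERT doxycycline replicate 3. The 72 h overlap ran from 12 to 18 (12 without HEK293 doxycycline replicate 2 or 3), and NUTM2 probe sets from 3 to 7 (3 without HEK293 mock 72 h replicate 1 or doxycycline 72 h replicate 2).

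Of 370 called gene results, 157 kept direction and call in all alternatives and left-out arrays, and of 8171 pairs of a result and an alternative 7044 kept both, 1125 lost the call and 2 reversed. Of the 25 called lists 15 kept their call throughout. Of 1100 such pairs 25 lost it. Uncalled gene results gained a call in 249 of 10442 pairs and uncalled lists in 124 of 6988, where the list pairs hold the same kinds of setting. Signal near background limits genes read by few dim probe sets, such as GABRE with 1 probe set at log2 0.81 in BJ-hTERT doxycycline cells at 24 h and GOLGA8B with 1 at 0.88 in mock cells.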

Other observations

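The list tests on mock cells over time were chosen after the data were seen, and the splits of the arrays were planned. Mock cells of both lines moved in groups of genes between 24 and 72 h. In BJ-hTERT cholesterol synthesis genes rose (10 of 19 called, mean log2 change 0.64, camera adjusted p = 0.0016 with an estimated correlation), as did fatty acid synthesis genes (5 of 10, 0.49, 0.0065), interferon-stimulated genes (8 of 21, 0.72, 0.027), fibroblast markers (5 of 16, 0.46, 0.0015), extracellular matrix genes (6 up and 2 down of 33, 0.28, 0.0014) and axon guidance genes (2 of 21, 0.32, 0.0014). NRF2 oxidative stress genes fell (5 of 15, -0.45, 0.0065), with G2 and mitosis genes (9 of 32, -0.42, 0.0065), replication genes (2 of 29, -0.23, 0.0056), histone genes (2 of 17, -0.25, 0.026), ATF4 genes (3 of 34, -0.26, 0.035) and ribosome biogenesis and MYC target genes (1 of 20, -0.14, 0.036). Endoplasmic reticulum stress genes rose slightly (1 of 18, 0.14, 0.046). In HEK293 ERK pathway output genes (4 of 26, -0.33, 0.00062) and ribosome biogenesis and MYC target genes (1 of 20, -0.16, 0.027) fell. Lists that rose there were ATF4 genes (1 of 34, 0.31, 0.027), and, with no member called by limma, matrix remodelling enzymes (0.29, 0.022), PI3K-AKT and FOXO targets (0.26, 0.048) and glycolysis and hypoxia genes (0.16, 0.045). Another 4 lists in HEK293 and 1 in BJ-hTERT were called with the preset correlation only: G2 and mitosis (-0.09), p53 targets (0.21), mitochondrial ribosome (-0.13) and cholesterol synthesis (0.19) in HEK293, and Hedgehog targets (0.28) in BJ-hTERT.

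With 10 splits of 6 arrays the splits are too few for a share under 0.05. The real split called 82 genes in HEK293 at 24 h, 210 in HEK293 at 72 h, 1534 in BJ-hTERT at 24 h and 1494 in BJ-hTERT at 72 h, and the highest other splits called 1, 1, 0 and 1 gene. For mock cells over time the real split called 64 genes in HEK293 and 321 in BJ-hTERT, and the highest other splits called 1 and 2. In each of these 6 comparisons 1 split, the real one, gave a count as large.

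In the remaining results 1 split, the real one, was as large. For the mean effect and the number of lists called, this argues against a chance assignment of labels among these arrays, but not for any single list. The other splits put the doxycycline effect into the spread, which lowers their counts. Chance between cultures was not tested, since the labels do not say that replicates are separate cultures. The mean effect called 1745 genes against 3 in the highest other of 100 splits. The 4 comparisons called 25 lists against 17 in the highest other of 100 splits. For the NUTM2 probe sets, 6 rose in all 4 comparisons against 0 in the highest other of 100. A split that calls almost nothing in 1 comparison cannot give a probe set that rises in all 4, so chance is not tested there. The overlap between lines was 7 genes at 24 h and 19 at 72 h against 0 in the highest other of 99 and 100 splits, but splits that call almost no genes in a line leave nothing to share. These splits therefore do not test whether the sharing exceeds chance. The one-sided Fisher's exact tests gave adjusted p = 0.10 for shared rises at 24 h, 0.0021 for shared rises at 72 h and 0.45 for shared falls at 72 h. Shared rises there include the induced NUTM2 genes.

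A transcript without a placed position, LOC100507412, chosen after its values were seen, was called in the same line as VSTM2B. It rose by 3.15 log2 at 24 h and 3.47 at 72 h in HEK293, and its changes in BJ-hTERT were 0.47 and -0.38.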
